A study of Mus musculus with 77 samples.

How the data were processed

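The series holds 77 Affymetrix mouse expression arrays, each from translating ribosome affinity purification (TRAP) of a single mouse. In TRAP, messenger RNA bound to a green-fluorescent ribosomal protein (EGFP-L10a) is pulled down from the cells that carry the tag. The tag was carried by direct pathway spiny projection neurons (dSPN, Drd1 line) or by indirect pathway spiny projection neurons (iSPN, Drd2 line). The deposited values are log2 expression per probe set, which the authors had brought to nearly the same distribution on every array. Per the submitters' processing notes RMA and the affy package were used, with no version stated. The deposited table held 45101 probe sets with values from 1.34 to 14.45 and array medians from 4.31 to 4.42. The sorted values of any array lay within 0.4 of the mean sorted values. Scanner files and detection calls were not used here, so the number of arrays sets the precision and no limit of detection was computed.

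Of the probe sets, 34958 carried a single gene symbol, 932 carried several and 9211 carried none, and those with several or none were left out. The Entrez identifiers of 34754 single-symbol probe sets were in the mouse gene table used here (GRCm38.p6), and no symbol was changed by it. Each gene was represented by its probe set with the highest mean. Of 18194 genes, 13271 with a mean above the 40th percentile of the probe set means (3.55 on the log2 scale) were tested.

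The arrays were mapped to 8 groups by line, surgery and drug. Chronic saline, low-dose levodopa and high-dose levodopa were each given to lesioned mice, and mock-lesioned mice received saline. The numbers in the sample titles fall into 7 stretches within which the animal number rises, called runs here, and each run lies within a line. What a run stands for is not given in the sources used here. A fit in limma 3.58.1 (R 4.3.3) with lmFit and eBayes covered all 77 arrays in 8 groups, with 69 residual degrees of freedom. A run term was to be kept if over 5% of the genes had a run effect at adjusted p. The share was 0%, so no run term was kept. At an unadjusted p under 0.05 the share was 4.22%, against 3.52% to 11.5% (median 5.82%) with 100 permutations of the run labels, of which 11 gave a share as low. The consensus correlation within runs was -0.021. Values with run as a fixed block and within runs are given beside the pooled ones.

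For each line the comparisons were lesion against mock, high dose against lesion with saline, low dose against lesion with saline, and high against low dose. Interaction terms compared the first 3 between lines as the effect in dSPN minus that in iSPN. The lines themselves were compared on the 20 mock-lesioned arrays, as dSPN minus iSPN. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison, and a gene was called at an adjusted p under 0.05. All changes are differences of log2 means, with the standard error (SE) of the fit. Group spreads are standard deviations (SD).

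Genes are named by a rule fixed with the other design choices before the data were examined. In the 6 comparisons of lesion, high dose and low dose it takes the 8 highest and 8 lowest changes among called genes, and up to 4 called members with the largest change from each list described. A panel of 12 genes (Drd1, Drd2, Pdyn, Penk, Tac1, Fos, Fosb, Junb, Arc, Egr1, Nr4a1 and Th) was read in every comparison. The other comparisons take the 5 highest, the 5 lowest and the panel.

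The 26 gene lists, fixed at the same stage, were immediate early genes, late activity-regulated plasticity genes, MAP kinase feedback regulators, neuropeptides and granins, dopamine and cAMP signalling, dSPN markers, iSPN markers, shared spiny projection neuron markers, glutamate receptors and scaffolds, GABA receptors and inhibitory synapse, potassium channels, sodium and calcium channels, actin and dendrite remodelling, sterol biosynthesis, oxidative phosphorylation, cytosolic ribosomal proteins, unfolded protein and heat shock response, proteasome, and markers of astrocytes, oligodendrocytes, microglia, endothelial and mural cells, cholinergic interneurons, GABA interneurons, dopaminergic terminals and cortical pyramidal neurons. Some genes stand in several lists. A list needed 5 measured members. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 26 lists within a comparison. Camera with an estimated correlation and fry were run beside it.

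Levodopa effects were compared with lesion effects across genes. Both share the lesioned saline arrays, which alone gives a negative relation. The covariance that those arrays give unchanged genes was taken from the fit, with the residual variance averaged over both lines. The correlation was also computed in 100 simulations of unchanged genes and in 100 random splits of the shared arrays between both effects.

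The alternatives were run as a fixed or as a random block, each line fitted on its own arrays, the arrays of 1 run, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, quantile normalization, median centring and array weights. Leaving out the arrays that were the single array of their group in a run was also planned, and named genes were read again without these. Chosen after seeing the data were leaving out each other array in turn for the counts of called genes, leaving out the outlying array of a panel gene, leaving out 4 arrays with a weight under 0.5, and the mean of the oligodendrocyte markers as a covariate. Other splits of the arrays were counted with 100 splits per comparison.

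The procedure was tested on simulated data in which 200 of 13271 genes were changed. In the lesion comparison of dSPN it recovered 45.6% of genes changed by 0.5, 89.4% of those changed by 1 and 100% of those changed by 2 on the log2 scale. In the low-dose comparison of iSPN it recovered 27.9%, 74.2% and 100%, and in the low-dose interaction 16.2%, 57.6% and 90.9%. False calls were 0.909% to 9.71% of the calls, the highest in the dose comparison of dSPN. A list moved in simulated data gave a camera p of 4.83e-26, and 3% of 100 unmoved lists had an unadjusted p under 0.05. Genes were simulated independently of each other, so this does not test the preset correlation. All arrays of a gene were simulated with the same spread, so the rates do not cover the larger spread of the iSPN arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Behavioural scores of the mice were not analysed here.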

Results

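Ribosome-bound messenger RNA of striatal spiny projection neurons was measured on arrays in male mice of 9 to 14 weeks. The toxin 6-hydroxydopamine (3.2 µg/µl), which kills dopamine neurons, had been injected into the medial forebrain bundle on 1 side, and the dorsal striatum of that side was taken. The direct pathway neurons (dSPN) gave 10 arrays after mock lesion with saline, 11 after lesion with saline, 12 after lesion with low-dose levodopa and 11 after lesion with high-dose levodopa. For the indirect pathway neurons (iSPN) these numbers were 10, 7, 8 and 8. Levodopa, the precursor of dopamine, was injected daily with 12 mg/kg benserazide. The low regimen was 1 mg/kg on days 1 to 3 and 2 mg/kg on days 4 to 9, and the high regimen was 3 mg/kg and then 6 mg/kg. The submitters chose the high regimen to bring on severe involuntary movements and the low regimen to restore limb use without them. The median correlation of an array with its own group lay between 0.939 and 0.9796. The number of arrays limits the precision: the median SE of a change was 0.15 for the lesion in dSPN and 0.17 in iSPN.

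The first comparison asked how the purified RNA of the lines differed in mock-lesioned mice. Each line held more of its own driver receptor. Drd1 was 11.80 ± 0.11 (SD, n = 10) in dSPN and 10.07 ± 0.37 in iSPN, a difference of 1.73 (SE 0.12, adjusted p = 4.2e-09). Drd2 was 7.55 ± 0.31 in dSPN and 12.42 ± 0.18 in iSPN, a difference of -4.87 (SE 0.12, adjusted p = 1.37e-17). The opioid peptide precursors split the same way, with Pdyn (prodynorphin) at 2.56 and Penk (proenkephalin) at -2.10. Tac1, the precursor of substance P, stood at 1.89. The genes furthest towards dSPN were Eya1 (5.96), Slc35d3 (2.89), Sfxn1 (2.82), Ebf1 (2.67) and Pdyn. Those furthest towards iSPN were Ttc12 (-7.74), Drd2, the orphan receptor Gpr6 (-4.27), the delta opioid receptor Oprd1 (-3.85) and Nt5e (-3.41). Of the 12 panel genes, Th, which encodes tyrosine hydroxylase, was also lower in dSPN (-0.78, adjusted p = 0.0267). Fos (0.42), Fosb (0.57), Junb (0.07), Arc (-0.38), Egr1 (-0.05) and Nr4a1 (0.26) did not pass.

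Among 13 measured dSPN markers 10 were higher and 1 lower in dSPN, or 10 and 2 when adjusted over the list alone (camera adjusted p = 1.58e-15). Among 11 iSPN markers 9 were lower in dSPN, also 9 when adjusted over the list alone (adjusted p = 1.2e-19). Both calls held with an estimated correlation (adjusted p = 6.01e-06 and 2.49e-06). Markers of other cells differed too: 9 of 15 oligodendrocyte markers and 5 of 15 astrocyte markers were lower in dSPN, or 11 and 5 adjusted over the list alone. The lists gave camera adjusted p = 2.23e-07 and 0.000474 (adjusted p = 0.116 and 0.0805 with an estimated correlation). In all, 2448 of 13271 genes differed, 1195 higher and 1253 lower in dSPN. With the oligodendrocyte marker mean as a covariate 426 passed. Dopamine and cAMP genes were lower in dSPN in 15 of 47 cases and higher in 8, or 16 and 8 adjusted over the list alone (adjusted p = 0.032, but adjusted p = 0.0554 with an estimated correlation). The lines share no run, so line and run cannot be told apart here.

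**Figure D1:**
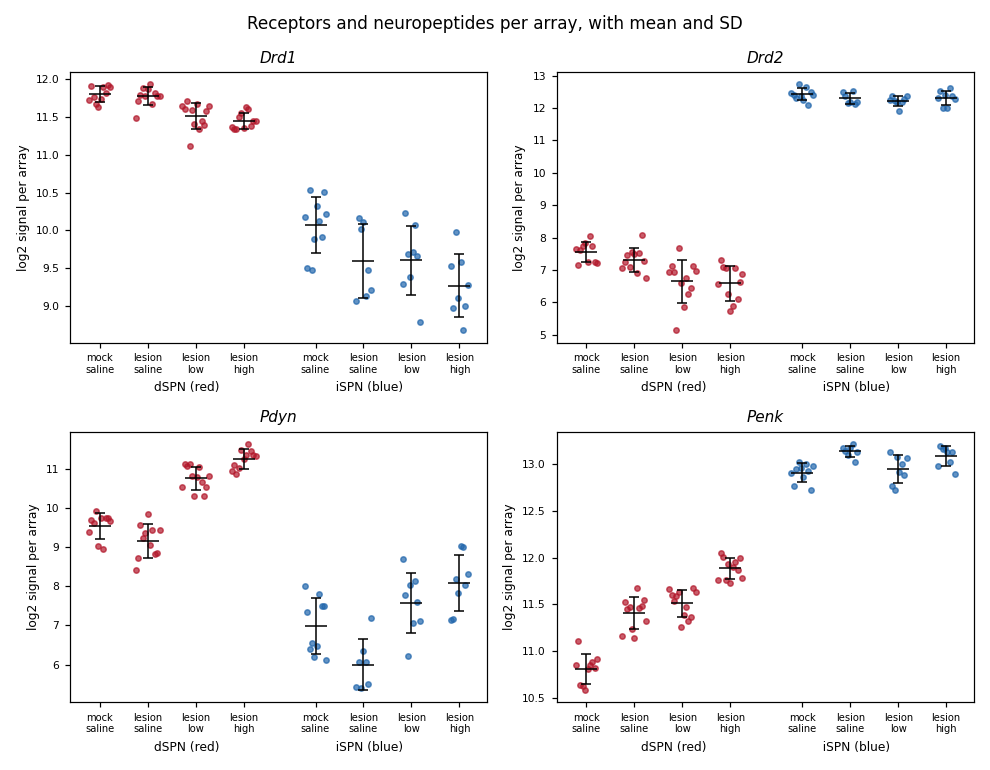
Log2 signal of Drd1, Drd2, Pdyn and Penk on each array (points), with the group mean and SD (bars), for dSPN in red and iSPN in blue. Drd2 averaged 7.55 in mock-lesioned dSPN and 12.42 in mock-lesioned iSPN, and Pdyn in dSPN averaged 9.16 after the lesion and 11.26 after high-dose levodopa.

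The next question was what loss of dopamine did to dSPN. After the lesion (n = 11 against 10) genes that follow neuronal activity fell. The growth-factor-induced peptide precursor Vgf fell by 2.14 (SE 0.17, adjusted p = 3.74e-15), from 9.17 ± 0.35 to 7.03 ± 0.68. The activity-induced transcription factors Egr2 (-1.74), Nr4a3 (-1.61) and Egr1 (-0.49, SE 0.08, adjusted p = 6.17e-05) fell, as did Arc (-0.76, adjusted p = 0.0102), a postsynaptic plasticity gene. The largest rises were those of Amhr2, a hormone receptor gene (2.35, SE 0.30, adjusted p = 5.28e-08), and Marcksl1, an actin-binding protein gene (1.69, SE 0.28, adjusted p = 2.82e-05). Penk, the marker peptide of iSPN, rose in dSPN by 0.60 (SE 0.06, adjusted p = 5.35e-11), from 10.81 ± 0.16 to 11.41 ± 0.17.

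The other rises at the top were those of the replication helicase gene Mcm6 (1.49), 6820408C15Rik (1.29), Fst (follistatin, 1.25), Trp53i11 (1.22), Dleu7 (1.22) and the transcription factor Sox11 (1.19). Of 2 Mcm6 probe sets above the filter only 1 rose. The largest falls beside Vgf, Egr2 and Nr4a3 were those of Mir670hg (-2.17), Ptges3l (-1.95), the interferon-inducible Ifi27l2a (-1.87), Wnt8b (-1.70) and C030013G03Rik (-1.68). Of the panel, Drd1 (-0.03), Drd2 (-0.23), Pdyn (-0.39, adjusted p = 0.497), Tac1 (-0.30, adjusted p = 0.0732), Fos (-0.63, adjusted p = 0.554), Fosb (0.13), Junb (-0.21), Nr4a1 (-0.52, adjusted p = 0.374) and Th (0.77, adjusted p = 0.123) did not pass.

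The brakes on MAP kinase signalling fell as a group: 7 of 22 fell and none rose, or 10 adjusted over the list alone, among them Dusp6 (-1.33), Spred3 (-1.23), Spry2 (-0.94) and Dusp14 (-0.81) (camera adjusted p = 4.74e-10). Of 33 immediate early genes 7 fell and none rose, or 12 adjusted over the list alone, with Crem (-0.82) and Tiparp (-0.80) beside the Egr and Nr4a genes (adjusted p = 4.03e-08). Of 26 late plasticity genes 4 fell, or 7 adjusted over the list alone, such as Scg2 (-0.75) and Rgs2 (-0.39), while Nptx1 rose by 0.73 (adjusted p = 2.03e-06). These calls held with an estimated correlation (adjusted p = 0.000314, 0.034 and 0.0334), as did a shift upward of 13 GABA interneuron markers with no called member (adjusted p = 0.00333, and 0.0334 with an estimated correlation).

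Oxidative phosphorylation genes shifted down, with 3 of 50 fallen, or 5 adjusted over the list alone, among them Cox8a (-0.33) and Atp5e (-0.27), all 3 small in size (adjusted p = 1.44e-07, but adjusted p = 0.218 with an estimated correlation). Beside these groups, markers of other cells shifted up: 1 of 15 astrocyte markers rose (Aldh1l1, 0.83) and none of 15 oligodendrocyte markers, also 1 and none adjusted over the list alone (adjusted p = 0.0176 and 0.0185, or adjusted p = 0.218 and 0.331 with an estimated correlation). Glutamate receptor genes (1 of 42 rose and 4 fell, 1 and 5 adjusted over the list alone, with Cacng3 at -0.52 and Neto2 at -0.51) and sterol synthesis genes (3 of 20 fell, 3 adjusted over the list alone, with Srebf2 at -0.70, Idi1 at -0.46 and Hmgcs1 at -0.35) had camera adjusted p = 0.0334 and 0.0467. With an estimated correlation these became adjusted p = 0.218 and 0.168. Actin and dendrite genes (2 of 52 rose, 3 rose and 1 fell adjusted over the list alone, with Stmn1 at 0.45) gave adjusted p = 0.012, with sodium and calcium channels at 0.0277, proteasome genes at 0.0185 and ribosomal protein genes at 0.0339. They were lost with an estimated correlation, at adjusted p = 0.113, 0.218, 0.36 and 0.461. Potassium channels (1 rose and 4 fell of 45, with Kcnj3 at 0.70, Kcna2 at -0.59, Kcnip3 at -0.58 and Kcnq3 at -0.56) did not pass as a list (adjusted p = 0.0716).

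The test called 329 of 13271 genes, 85 up and 244 down, of which 54 changed over 2-fold. A fixed block for run left 88, and array weights gave 776. Fitted on run 1 alone, with 5 lesioned and 4 mock arrays, 7 passed and 4 of 54 named genes kept their call. In the fit with the block Mcm6 (adjusted p = 0.263), Fst (0.115), Dleu7 (0.666), Wnt8b (0.517), C030013G03Rik (0.138), Crem (0.167), Tiparp (0.458), Dusp14 (0.167), Nptx1 (0.0779), Aldh1l1 (0.104) and Arc (0.454) were no longer called. Nor were Stmn1 (0.0872), Cox8a (0.629), Atp5e (0.525), Cacng3 (0.358), Neto2 (0.218), Srebf2 (0.523), Kcnj3 (0.298), Kcna2 (0.0705) and Kcnip3 (0.112), so that 30 of 54 named genes lost their call. All 329 called genes kept their sign in that fit to the same arrays, at a median 0.98 of the pooled change. With dSPN arrays alone in the fit 554 genes passed.

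**Figure D2:**
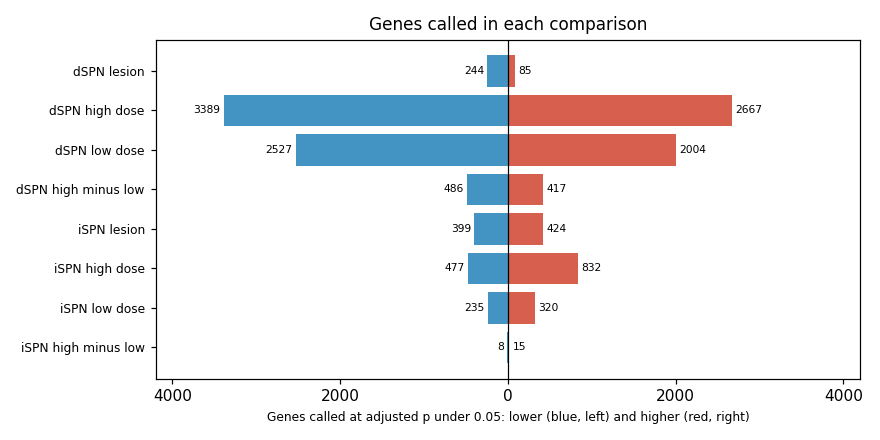
Number of genes called at an adjusted p under 0.05 in 8 comparisons, with genes lower in the first-named group as blue bars to the left and higher as red bars to the right. High-dose levodopa in dSPN gave 3389 lower and 2667 higher genes, and the dose comparison in iSPN gave 8 lower and 15 higher.

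High-dose levodopa was then compared with saline in lesioned mice to ask what the dyskinesia-inducing regimen did to dSPN (n = 11 against 11). Genes that neurons switch on with activity rose steeply. The orphan nuclear receptors Nr4a2 (5.98, SE 0.26, adjusted p = 2.08e-31) and Nr4a3 (5.89) and cyclooxygenase-2 (Ptgs2, 5.59, SE 0.22, adjusted p = 2.39e-34) led the list. Arc rose from 6.43 ± 0.36 to 10.59 ± 0.17, by 4.16 (SE 0.18, adjusted p = 1.69e-31), and Fosb from 7.87 ± 0.41 to 11.67 ± 0.21, by 3.80 (SE 0.21, adjusted p = 3.05e-26). The opioid precursor Pdyn rose by 2.10 (SE 0.22, adjusted p = 8.23e-13), from 9.16 ± 0.43 to 11.26 ± 0.25.

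The other top rises were Tinf2, of the telomere-capping complex (5.48), Shisa2 (5.05), Apold1 (4.91), the somatostatin receptor Sstr2 (4.74) and Serpinb2 (4.74). The largest falls were Notch2 (-2.78), Trim66 (-2.74), the cAMP-gated exchange factor Rapgef3 (-2.73), 2900026A02Rik (-2.64), Ddit4l (-2.55), Zkscan16 (-2.41), Hadh (-2.40) and Igfbp5 (-2.39). In the panel Fos (3.64, SE 0.38, adjusted p = 8.3e-13), Nr4a1 (3.14), Junb (1.10), Egr1 (1.05), Th (2.85, SE 0.26, adjusted p = 2.6e-15), Tac1 (0.56) and Penk (0.48) rose. Drd2 (-0.72, adjusted p = 0.000268) and Drd1 (-0.32, SE 0.13, adjusted p = 0.0313) fell.

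Of 33 immediate early genes 31 rose and none fell, or 32 adjusted over the list alone, with Egr2 at 4.38 and Ier3 at 4.35 (camera adjusted p = 1.99e-41). Of 26 late plasticity genes 19 rose and 1 fell, the same adjusted over the list alone, with activin subunit Inhba (4.49), the prohormone convertase Pcsk1 (4.31) and the synaptic pentraxin Nptx2 (4.26) (adjusted p = 8.06e-18). MAP kinase phosphatases rose with them: 12 of 22 feedback regulators rose and 2 fell, unchanged over the list alone, led by Dusp4 (4.3), Dusp14 (3.81) and Dusp5 (2.71) (adjusted p = 5.11e-09). Among 22 neuropeptide and granin genes 12 rose and 2 fell, or 12 and 4 adjusted over the list alone, including Vgf (3.15), Nts (neurotensin, 2.77) and Scg2 (2.56) (adjusted p = 9.02e-05). Ribosomal protein genes rose broadly, 29 of 34 or 31 adjusted over the list alone, with Rps25 (1.71), Rpl14 (1.45) and Rps19 (0.79) (adjusted p = 8.62e-14). With an estimated correlation all 5 lists held (adjusted p = 1.23e-07, 2.29e-05, 0.000452, 0.033 and 0.0371).

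Respiratory chain genes also shifted up, 33 of 50 risen and 2 fallen both over all genes and adjusted over the list alone, as Atp5l (0.68) and Atp5d (0.66) (adjusted p = 1.13e-06, but adjusted p = 0.209 with an estimated correlation). Stress and chaperone genes (15 of 34 rose and 2 fell, 15 and 2 adjusted over the list alone, led by Dnajb5 at 2.64 and Ddit3 at 0.99) and sterol synthesis genes (8 of 20 rose and 2 fell, 8 and 2 adjusted over the list alone, with Idi1 at 1.62, Pmvk at 1.43, Cyp51 at 1.14 and Lss at -1.30) gave adjusted p = 0.000964 and 0.0229. With an estimated correlation these were adjusted p = 0.142 and 0.0757. Beside these groups glial markers fell: 11 of 15 oligodendrocyte markers, 12 adjusted over the list alone, with the myelin genes Mal (-1.74) and Mbp (-1.37, SE 0.19, adjusted p = 9.43e-09), and 8 of 15 astrocyte markers, 8 adjusted over the list alone, with Gja1 (-1.27) and Slc1a2 (-1.03) (camera adjusted p = 0.000141 and 0.0491). These list calls were lost with an estimated correlation (adjusted p = 0.193 and 0.34).

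Some lists of neuronal genes shifted down in the test with the preset correlation alone. Of 19 shared spiny neuron markers 11 fell and 3 rose, the same adjusted over the list alone, with Strn (-0.81) and the adenylyl cyclase Adcy5 (-0.74) lower and Gad1 (0.64) higher (adjusted p = 0.0113). Of 11 iSPN markers 8 fell and 1 rose, 8 and 2 adjusted over the list alone, including Grik3 (-1.33), Gucy1a1 (-1.03) and Gpr6 (-0.77) (adjusted p = 0.0417). These markers are dim in dSPN (mean 7.1 after lesion with saline and 6.62 at the high dose, against 9.18 in lesioned iSPN), so a change within dSPN is not told apart from less carried-over RNA of iSPN. Potassium channel genes split, 19 of 45 fallen and 5 risen, the same adjusted over the list alone, with Kcnj9 (-2.08), Kcnd3 (-1.64) and Kcng1 (-1.36) against Kcnn3 (1.80) (adjusted p = 0.0491). These 3 calls were lost with an estimated correlation (adjusted p = 0.0886, 0.114 and 0.196).

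The remaining lists did not pass in dSPN at the high dose. Dopamine and cAMP genes moved both ways (12 of 47 rose and 23 fell, adjusted p = 0.526), with Htr1b (1.71) against Oprd1 (-1.47), the kappa opioid receptor Oprk1 (-1.19) and Chrm1 (-1.18). So did glutamate receptor genes (11 rose and 13 fell of 42, adjusted p = 0.865), with Homer1 (2.03) and Grm4 (1.65) against Grin2b (-1.09), and actin genes (16 rose and 20 fell of 52, adjusted p = 0.838), with Nrp1 at 2.46 and Marcksl1 at -1.29. Of 24 sodium and calcium channels 10 fell and 3 rose, with Cacna1h at -1.65 (adjusted p = 0.11), and of 13 dSPN markers 5 fell and 4 rose, with Nnat (2.58) and Stmn2 (1.14) against Gpr149 (-1.42) (adjusted p = 0.468). Of 7 dopaminergic terminal markers 3 rose, namely Th, Slc18a2 (1.19) and Nr4a2, which is also on the immediate early gene list, and Dlk1 fell (-0.90). The list gave adjusted p = 0.0615. GABA receptors (3 rose and 5 fell of 15, adjusted p = 0.93), proteasome genes (10 rose and 3 fell of 31, 0.0646), microglia (2 rose and 1 fell of 11, with Cd68 at 1.69, 0.655), GABA interneuron (2 rose and 2 fell of 13, 0.963), cholinergic (1 fell of 6, 0.79), cortical (1 fell of 6, 0.963) and endothelial and mural markers (none of 9 called, 0.963) gave no list call.

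In all 6056 of 13271 genes were called, 2667 up and 3389 down, and 1341 of them changed over 2-fold. Fitted on run 2 alone, with 9 high-dose and 6 saline arrays, 5228 passed and 102 of 109 named genes kept their call, and 5547 genes passed with run as a fixed block.

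**Figure D3:**
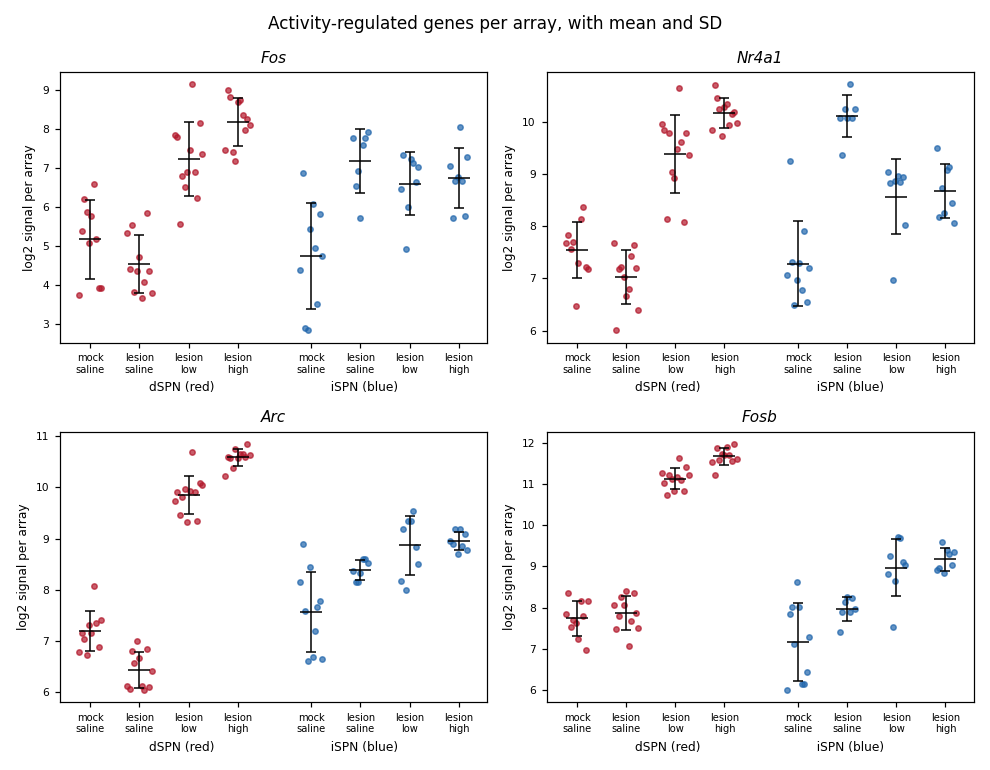
Log2 signal of Fos, Nr4a1, Arc and Fosb on each array (points), with the group mean and SD (bars), for dSPN in red and iSPN in blue. In dSPN Arc averaged 6.43 after the lesion and 10.59 after high-dose levodopa, and in iSPN Nr4a1 averaged 7.28 after mock lesion and 10.11 after the lesion.

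Low-dose levodopa, meant to restore movement without dyskinesia, moved much of the same program in dSPN (n = 12 against 11). Nr4a3 rose by 5.55 (SE 0.25, adjusted p = 1.09e-30), Arc by 3.42 (SE 0.18, adjusted p = 6.09e-27) and Fosb by 3.26 (SE 0.20, adjusted p = 6.92e-23). Pdyn rose by 1.61 (SE 0.22, adjusted p = 6.14e-09) and Th by 1.49 (SE 0.25, adjusted p = 2.02e-06). The other top rises were Apold1 (4.46), Nr4a2 (4.43), Shisa2 (4.4), Egr2 (4.36), Tinf2 (4.35), Ubash3b (4.20) and Inhba (4.13). The largest falls were Igfbp5 (-2.20), Rapgef3 (-2.18), Plpp3 (-2.08), S1pr5 (-2.04), Mcm6 (-2.0), Notch2 (-1.98), Fam117a (-1.89) and Prr15 (-1.87). Of the panel Fos (2.68), Nr4a1 (2.37), Egr1 (1.05), Junb (0.65) and Tac1 (0.36, adjusted p = 0.00145) also rose and Drd2 fell by 0.67 (adjusted p = 0.000859). Drd1 (-0.26, adjusted p = 0.0979) and Penk (0.11, adjusted p = 0.169) did not pass.

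Immediate early genes rose in 30 of 33 cases and late plasticity genes in 16 of 26 with 1 fall, or 30 and 16 with 2 falls adjusted over the list alone, as Fosl2 (4.02), Ptgs2 (3.92), Nptx2 (3.62) and the chromatin factor Baz1a (3.62) (camera adjusted p = 6.89e-47 and 8.79e-19). MAP kinase regulators followed (12 of 22 rose and 1 fell, 14 and 1 adjusted over the list alone, led by Dusp14 at 3.43 and Dusp4 at 3.27, adjusted p = 2.85e-12), as did ribosomal protein genes (27 of 34 rose, 29 adjusted over the list alone, with Rpl14 at 1.33, adjusted p = 1.36e-14). The iSPN markers fell in 8 of 11 cases, also 8 adjusted over the list alone, with Gpr6 (-1.18), Grik3 (-1.10) and Plxdc1 (-0.96) (adjusted p = 0.00332), with the same limit as at the high dose. These 5 list calls held with an estimated correlation (adjusted p = 2.01e-08, 1.31e-05, 2.61e-05, 0.0294 and 0.0263).

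Neuropeptides rose (9 of 22, with 3 fallen, and the same adjusted over the list alone), among them Pcsk1 (3.59), Vgf (2.49) and Cartpt (1.97), at adjusted p = 0.00123, or adjusted p = 0.0744 with an estimated correlation. Oxidative phosphorylation genes rose in 29 of 50 cases and fell in 3, or 30 and 3 adjusted over the list alone (Atp5l, 0.58), at adjusted p = 4.33e-07, or adjusted p = 0.173 with an estimated correlation. Glial markers fell beside them, 12 of 15 for oligodendrocytes (Ugt8a, -1.69, and Mag, -1.53) and 6 of 15 for astrocytes (Gja1, -1.53), with the same counts adjusted over the list alone (adjusted p = 8.19e-06 and 0.00374, or adjusted p = 0.117 and 0.129 with an estimated correlation). Sodium and calcium channels (2 of 24 rose and 12 fell, 2 and 13 adjusted over the list alone, with Cacna1h at -1.02) and potassium channels (4 of 45 rose and 16 fell, 4 and 18 adjusted over the list alone, with Kcnj9 at -1.58) had adjusted p = 0.00984 and 0.0321, or adjusted p = 0.117 and 0.15 with an estimated correlation. Stress and chaperone genes, proteasome genes and shared spiny neuron markers also passed (adjusted p = 0.00759, 0.0171 and 0.0215) and were lost with an estimated correlation (adjusted p = 0.195, 0.459 and 0.117). For 7 dopaminergic terminal markers the test pointed up (adjusted p = 0.0461, or adjusted p = 0.117 with an estimated correlation) and the mean was 0.86, but the median was -0.02, with 3 risen, also 3 adjusted over the list alone. Among the 3 was Nr4a2, a top rise that is also on the immediate early gene list. The other 11 lists did not pass.

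At the low dose 4531 genes were called, 2004 up and 2527 down, 655 of them over 2-fold. No run held arrays of both groups, so no value within a run can be had, and with run as a fixed block 1847 genes passed. In that fit Rapgef3 (adjusted p = 0.49), Plpp3 (0.0695), Fam117a (0.291), Prr15 (0.414), Plxdc1 (0.193), Tac1 (0.0884) and Drd2 (0.419) were no longer called, and 26 of 106 named genes lost their call.

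Set against each other, high and low dose shared 1778 genes up and 2230 down in dSPN, where 403 and 645 would be shared if the calls were independent, and none went opposite ways. Across genes, which are not independent replicates, the effects correlated at 0.93 (Spearman 0.89). The shared saline arrays alone gave 0.51 in simulated unchanged genes, and splitting them between both effects gave 0.86.

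The dose comparison in dSPN (n = 11 against 12) called 903 genes, 417 higher and 486 lower at the high dose. Th stood 1.36 higher (SE 0.25, adjusted p = 0.00016) and Penk 0.37 higher (SE 0.06, adjusted p = 7.62e-06). The largest differences up were Lipg, an endothelial lipase gene (2.11, SE 0.25, adjusted p = 8.75e-09), Trh, the precursor of thyrotropin-releasing hormone (1.92), Serpinb2 (1.80), Sdcbp2 (1.79) and Gprc5a (1.69). Lowest were Gng2 (-1.44), Gm6556 (-1.24), the clock gene Arntl (-1.23, adjusted p = 1.78e-06), Tunar (-1.19) and Hps3 (-1.18). For Hps3 only 1 of 2 probe sets above the filter was lower. Arc (0.74, adjusted p = 0.00481), Nr4a1 (0.77, adjusted p = 0.0389) and Junb (0.45, adjusted p = 0.00269) were higher. Values for Pdyn (0.49, adjusted p = 0.175), Fos (0.96, 0.116), Fosb (0.54, 0.0976), Tac1 (0.20, 0.2), Egr1 (0.00, 0.996), Drd1 (-0.06) and Drd2 (-0.05) did not pass.

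Of 33 immediate early genes 14 were higher at the high dose and of 26 late plasticity genes 9, with none lower, or 25 and 14 adjusted over the list alone (camera adjusted p = 1.14e-15 and 6.57e-10, and adjusted p = 0.00298 and 0.00329 with an estimated correlation). Neuropeptides (6 of 22 higher, 7 adjusted over the list alone, adjusted p = 0.000278), ribosomal protein genes (none called, 0.000938), stress genes (2 of 34 higher and 1 lower, the same over the list alone, 0.00646) and MAP kinase regulators (6 of 22 higher and 1 lower, 8 and 2 adjusted over the list alone, 0.0275) were lost with an estimated correlation (adjusted p = 0.053, 0.463, 0.248 and 0.236). With run as a fixed block 174 genes passed, and Arc (adjusted p = 0.0681), Nr4a1 (0.523), Junb (0.135), Gng2 (0.0941), Gm6556 (0.0658) and Hps3 (0.17) did not. Array weights gave 1375. Fitted on run 3 alone (2 against 11 arrays) 7 passed and 1 of 15 named genes kept its call. The call of Nr4a1 also ended without low-dose replicate 5 (0.74).

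In iSPN the lesion (n = 7 against 10) raised activity-dependent genes. Nr4a1 rose by 2.83 (SE 0.29, adjusted p = 1.54e-11), from 7.28 ± 0.81 to 10.11 ± 0.40, and Fos by 2.43 (SE 0.44, adjusted p = 7.71e-05). The peptide precursors Cartpt (3.89, SE 0.39, adjusted p = 1.14e-11), Nts (2.60), Scg2 (1.90, SE 0.14, adjusted p = 2.11e-17) and Vgf (1.65) rose, and the annexin gene Anxa3 rose by 4.24 (SE 0.33, adjusted p = 1.97e-16). Both GABA-synthesising enzymes rose, Gad1 by 0.84 (SE 0.12, adjusted p = 3.03e-07) and Gad2 by 0.57 (SE 0.07, adjusted p = 1.71e-09). In the iSPN samples RNA of dSPN markers fell, with Pdyn at -0.99 (SE 0.26, adjusted p = 0.00889), Isl1 at -0.93, Drd1 at -0.47 (adjusted p = 0.0356) and Tac1 at -0.42 (adjusted p = 0.00921, but -0.27 and adjusted p = 0.106 without lesioned saline replicate 7). The dSPN markers averaged 7.45 in mock-lesioned and 7.04 in lesioned iSPN, against 9.4 in mock-lesioned dSPN, so less carried-over RNA of dSPN is not told apart from a change within iSPN.

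The other top rises were C030013G03Rik (3.27), Nptx2 (2.59) and Aard (2.24). The largest falls were the glutathione peroxidase gene Gpx6 (-2.60), the sulfatase gene Sulf1 (-2.22), Wnt8b (-2.11), Fam163b (-1.96), S100a10 (-1.93), Fhit (-1.85), Wnt7a (-1.71) and Fam241b (-1.67). In the panel Th (1.15, adjusted p = 0.01), Arc (0.82, 0.00878), Fosb (0.80, 0.0289) and Penk (0.23, 0.033) rose. Drd2 (-0.12), Egr1 (0.07) and Junb (0.29, 0.163) did not pass.

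Late plasticity genes rose in 10 of 26 cases and immediate early genes in 11 of 33, with none fallen, or 11 and 14 adjusted over the list alone, as Fosl2 (1.82), Ier3 (1.61) and Inhba (1.55) (camera adjusted p = 1.87e-13 and 2.21e-11). Of 22 neuropeptides 6 rose and 2 fell, or 6 and 3 adjusted over the list alone (adjusted p = 0.000425), and of 13 dSPN markers 4 fell and Nnat rose (0.90), or 8 and 1 adjusted over the list alone (adjusted p = 0.000767). These calls held with an estimated correlation (adjusted p = 0.000536, 0.0131, 0.0478 and 0.0232). Proteasome genes shifted up with 2 of 31 risen, also 2 adjusted over the list alone (Psmd7, 0.41), at adjusted p = 0.00414, or adjusted p = 0.591 with an estimated correlation. Lists of glial markers did not pass (oligodendrocytes 0.354, astrocytes 0.35), nor did MAP kinase regulators (5 rose and 2 fell of 22, adjusted p = 0.0548) with Dusp14 at 1.26 and Dusp5 at 0.94.

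The test called 823 genes, 424 up and 399 down, 162 of them over 2-fold. It takes 1 spread per gene for both lines although iSPN arrays varied more, so this count is not comparable with that of dSPN. No run held enough arrays of both groups for a fit within it. With run as a fixed block 106 genes passed, and Fos (adjusted p = 0.116), Arc (0.207), Fosb (0.205), Penk (0.52), Pdyn (0.127), Isl1 (0.593), Drd1 (0.423), Tac1 (0.844), Th (0.674), Nnat (0.181), Gpx6 (0.0948), Wnt8b (0.127), S100a10 (0.205), Dusp5 (0.0828), Psmd7 (0.559) and Fam241b (0.405) did not. In that fit to the same arrays 821 of the 823 called genes kept their sign, at a median 0.97 of the pooled change. The call of Drd1 ended without mock replicate 7 (-0.46) or without lesioned saline replicate 5 (-0.39). That of Fosb ended without the former (0.69) and that of Penk without the latter (0.21). The call of Tac1 also ended with array weights (-0.33, adjusted p = 0.082), with iSPN arrays alone in the fit and with the mean of all probe sets (-0.18, 0.273). With iSPN arrays alone in the fit 350 genes passed, and with array weights 438, which kept 39 and 49 of 64 named genes. Run as a fixed block kept 26 of the 64.

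High-dose levodopa in iSPN (n = 8 against 7) raised Pdyn and Tac1, peptide genes of the dSPN type, and lowered Nr4a1, Vgf and Scg2, which had risen after the lesion. Pdyn rose by 2.09 (SE 0.27, adjusted p = 2.97e-08), from 6.00 ± 0.64 to 8.09 ± 0.72, and Tac1 by 0.76 (SE 0.11, adjusted p = 1.5e-06). Rnd1 (3.46, SE 0.40, adjusted p = 1.69e-09), Wfdc18 (3.42), Nr4a2 (2.52) and the growth arrest genes Cdkn1a (2.21) and Gadd45g (2.14, SE 0.19, adjusted p = 3.52e-14) rose. Nr4a1 fell by 1.44 (SE 0.30, adjusted p = 0.000635), Vgf by 1.05 and Scg2 by 0.96.

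The remaining top rises were Pnmt, which encodes the adrenaline-forming enzyme (2.41), Mapkapk3 (2.39), Hic1 (2.34) and Fblim1 (2.16). The largest falls were C030013G03Rik (-2.30), the ceramide synthase gene Cers4 (-1.80), Fadd (-1.78), 9330179D12Rik (-1.69), Ntng1 (-1.65), Gask1b (-1.64), Trmt9b (-1.55) and Slc27a1 (-1.47). In the panel Fosb rose by 1.20 (adjusted p = 0.000582) and Egr1 fell by 0.33 (adjusted p = 0.0226). A constant share of 11.1% of dSPN RNA, as needed for Pdyn, would alone give Fosb a rise of 1.23. A rise of Fosb within iSPN is thus not told apart from carried-over RNA. That share would give 0.99 for Cdkn1a, which rose by more, and 0.11 for Egr1, which fell. Drd1 (-0.33, 0.171), Drd2 (0.02), Penk (-0.05), Fos (-0.43, 0.647), Arc (0.57, 0.0889), Junb (-0.05) and Th (0.48) did not pass.

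Chaperone and stress genes rose in 8 of 34 cases and none fell, or 10 adjusted over the list alone, among them the endoplasmic reticulum proteins Sdf2l1 (1.29), Manf (1.11) and Hspa5 (0.81) (camera adjusted p = 7.3e-06). Oxidative phosphorylation genes rose in 10 of 50, or 20 adjusted over the list alone, by small amounts such as 0.42 for Cyc1 and 0.34 for Atp5l (adjusted p = 6.9e-06), beside a downward shift of oligodendrocyte markers with 1 of 15 fallen, also 1 adjusted over the list alone (Pdgfra, -0.90, adjusted p = 0.00124). MAP kinase regulators fell, 7 of 22 with 1 risen, or 9 and 2 adjusted over the list alone, with Dusp6 (-1.22), Spry2 (-0.81) and Spred2 (-0.77) (adjusted p = 0.000199). These 4 calls were lost with an estimated correlation (adjusted p = 0.0749, 0.37, 0.37 and 0.0749).

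Immediate early genes divided, 10 of 33 risen and 5 fallen, or 14 and 5 adjusted over the list alone (adjusted p = 0.00267, or adjusted p = 0.37 with an estimated correlation). Most of this list rose in dSPN, so carried-over RNA of dSPN is not told apart for the risen members. Ribosomal protein genes (2 of 34 rose, none adjusted over the list alone), sodium and calcium channels (2 of 24 fell, also 2 over the list alone, with Cacna1e at -0.46), sterol synthesis genes (2 of 20 rose and 1 fell, 6 and 1 adjusted over the list alone, with Mvd at 1.13) and GABA receptors (2 of 15 fell, also 2 over the list alone, with Gphn at -0.65 and Gabrb2 at -0.57) had adjusted p = 0.0017, 0.00536, 0.011 and 0.0194. All 4 were lost with an estimated correlation (adjusted p = 0.585, 0.169, 0.0749 and 0.315). The other 17 lists did not pass.

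The high dose called 1309 genes in iSPN, 832 up and 477 down, 203 of them over 2-fold. Fitted on run 6 alone (8 against 2 arrays) 61 passed and 11 of 74 named genes kept their call. A fixed block for run left 249 genes, and 577 passed with iSPN arrays alone in the fit and 855 without the 4 arrays of low weight. With the fixed block Nr4a1 (adjusted p = 0.15), Tac1 (0.0796), Vgf (0.0557), Egr1 (0.389), Hic1 (0.13), Cers4 (0.16), Fadd (0.233), Ntng1 (0.0782), Slc27a1 (0.0875), Sdf2l1 (0.0685), Manf (0.103) and Hspa5 (0.0536) were not called. Nor were Cyc1 (0.32), Atp5l (0.679), Pdgfra (0.455), Cacna1e (0.13), Gphn (0.106) and Gabrb2 (0.0679), so that 47 of 74 named genes lost their call. Pdyn was (2.13, 0.000292).

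Under low-dose levodopa (n = 8 against 7) iSPN showed fewer called genes than at the high dose in the pooled fit, but more with run as a fixed block. Part of the leading genes was shared with the high dose. Pdyn rose by 1.58 (SE 0.27, adjusted p = 6.81e-05), Tac1 by 0.60 (SE 0.11, adjusted p = 0.000335), Gadd45g by 1.51 (SE 0.19, adjusted p = 3.9e-08) and Cdkn1a by 1.98 (SE 0.28, adjusted p = 1.23e-06). Hic1 (2.56), Mapkapk3 (2.37), Rnd1 (2.06), Fblim1 (1.76), the calcium-binding interneuron marker Pvalb (1.74), Pnmt (1.72) and Nr4a2 (1.60) completed the top rises. Nr4a1 fell by 1.55 (SE 0.30, adjusted p = 0.000493) and Vgf by 1.36 (SE 0.21, adjusted p = 7.24e-06), with C030013G03Rik (-1.63), 0610040B10Rik (-1.58), Sema5b (-1.52), Ntng1 (-1.37), Csf2ra (-1.35) and Neu3 (-1.34). For Csf2ra only 1 of 2 probe sets above the filter fell. Fosb rose by 1.00 (adjusted p = 0.01) and Egr1 fell by 0.34 (0.0338). Whether carried-over RNA of dSPN gave the rise of Fosb or other activity genes was not tested at the low dose. Drd1 (0.00), Drd2 (-0.07), Penk (-0.19, 0.132), Fos (-0.58, 0.577), Arc (0.48, 0.233), Junb (-0.18) and Th (0.46) did not pass.

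Channel and inhibitory synapse genes shifted down: 2 of 24 sodium and calcium channels fell (Cacna1e, -0.52) and 2 of 15 GABA receptor genes (Gabrb2, -0.67), or 2 and 3 adjusted over the list alone (camera adjusted p = 0.000434 and 0.000817). MAP kinase regulators fell in 4 of 22 cases, or 6 adjusted over the list alone, with Spry2 at -0.75 (adjusted p = 0.00372). With an estimated correlation these were adjusted p = 0.0783, 0.0821 and 0.115. Immediate early genes (5 of 33 rose and 2 fell, 8 and 4 adjusted over the list alone), oxidative phosphorylation genes (none called, nor over the list alone) and sterol synthesis genes (1 of 20 rose, 2 adjusted over the list alone, with Mvd at 0.74) had adjusted p = 0.0307, 0.0386 and 0.0386, or adjusted p = 0.491, 0.606 and 0.115 with an estimated correlation. The other 20 lists did not pass.

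In total 555 genes were called, 320 up and 235 down, 104 of them over 2-fold. Fitted on run 7 alone (8 against 4 arrays) 4 passed and none of 54 named genes kept its call. A fixed block for run left 470, but Mapkapk3 (adjusted p = 0.0538), C030013G03Rik (0.0953), Sema5b (0.0516) and Egr1 (0.0987) were not among them. In that fit 20 of 54 named genes lost their call. With iSPN arrays alone in the fit 153 passed, and 34 of 54 named genes lost their call, among them Pvalb. Array weights ended the call of 17.

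The doses shared 245 genes up and 142 down in iSPN, against 20.1 and 8.45 if independent, and none in opposite directions. The correlation across genes was 0.72 (Spearman 0.68), with 0.53 in simulated unchanged genes and 0.31 when the saline arrays were split. Between doses (n = 8 against 8) iSPN differed in 23 genes, with Wfdc18 (1.95, SE 0.36, adjusted p = 0.00187), Ptgs2 (1.43), Rasl11b (0.83), Klf10 (0.79) and Synpr (0.64) highest. Slc31a2 (-1.39), Ubr3 (-0.89), Nkain4 (-0.88), Fbxo2 (-0.74) and 6820431F20Rik (-0.56) were lowest. None of the 12 panel genes passed, with Pdyn at 0.51 (adjusted p = 0.48) and Drd1 at -0.33 (0.396). Oligodendrocyte markers shifted down at the high dose with none of 15 called but 5 adjusted over the list alone (adjusted p = 5.57e-07). Beside this stood upward shifts of stress genes (6.26e-05), oxidative phosphorylation genes (0.000189), proteasome genes (0.0261) and late plasticity genes (0.0367), of which oxidative phosphorylation and proteasome genes pointed down with run as a fixed block. These 5 calls were lost with an estimated correlation (adjusted p = 0.246, 0.246, 0.542, 0.627 and 0.542). With run as a fixed block no gene passed, and 1016 had an unadjusted p under 0.05 against 1395 without the block. The count of 23 moved to between 12 and 53 when single arrays were left out and to 158 with a random block. No run held arrays of both doses.

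Whether the lines responded differently was tested with interaction terms, as the change in dSPN minus that in iSPN. The responses of activity genes to the lesion differed: the difference was -3.79 for Vgf (SE 0.26, adjusted p = 8.83e-19), -3.35 for Nr4a1, -3.05 for Fos (adjusted p = 0.000216), -1.58 for Arc (5.64e-05) and -0.56 for Egr1 (0.00247), and it was 0.37 for Penk (0.00724). Vgf and Arc fell in dSPN and rose in iSPN, whereas Nr4a1 and Fos passed in iSPN alone and Egr1 in dSPN alone. Of 33 immediate early genes 15 and of 26 late plasticity genes 9 differed towards iSPN, with none the other way, or 20 and 12 adjusted over the list alone, and 9 of 22 MAP kinase regulators did, 10 over the list alone. The lists gave camera adjusted p = 3.19e-17, 6.38e-17 and 6.97e-08, and adjusted p = 0.000738, 7.77e-05 and 0.00115 with an estimated correlation. Neuropeptides had a median of 0.06 but a mean of -0.40 and a test pointing down (adjusted p = 0.0474, or adjusted p = 0.246 with an estimated correlation). Of the genes called in both lines after the lesion, 58 moved in opposite directions, 8 rose and 13 fell in both, where independence gives 10.4, 2.72 and 7.34.

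For the high dose the responses differed by 5.33 for Nr4a3, 4.92 for Shisa2, 4.59 for Nr4a1, 4.07 for Fos, 3.59 for Arc, 2.59 for Fosb and 2.37 for Th. For Rnd1 the value was -3.65. Immediate early genes were more strongly raised in dSPN in 28 of 33 cases, or 29 adjusted over the list alone (adjusted p = 1.52e-39, and adjusted p = 2.34e-07 with an estimated correlation). So were late plasticity genes (17 of 26, with 1 the other way, or 18 and 1 adjusted over the list alone) and MAP kinase regulators (12 of 22, or 14). Their camera adjusted p were 1.26e-20 and 4.16e-16, or adjusted p = 3.08e-06 and 1.63e-06 with an estimated correlation. Neuropeptides (9 of 22 with 1 the other way, or 10 and 1 adjusted over the list alone) gave adjusted p = 5.47e-05, and adjusted p = 0.0246 with an estimated correlation. Ribosomal protein genes (18 of 34, or 21 adjusted over the list alone) gave adjusted p = 6.22e-08, but adjusted p = 0.198 with an estimated correlation. No difference passed for Pdyn (0.01, adjusted p = 0.992), Tac1 (-0.20, 0.341) or Drd1 (0.01). The low dose gave 4.94 for Nr4a3, 3.92 for Nr4a1, 3.27 for Fos and 2.94 for Arc, with 26 of 33 immediate early genes, also 26 over the list alone (adjusted p = 7.61e-43, and adjusted p = 7.6e-08 with an estimated correlation). Beside these, 7 of 15 oligodendrocyte markers were more strongly lowered in dSPN at the low dose, or 12 adjusted over the list alone (adjusted p = 2.48e-05, but adjusted p = 0.199 with an estimated correlation). No difference passed there for Pdyn (0.03), Tac1 (-0.25) or Th (1.03, adjusted p = 0.0749). The interaction called 645 genes for the lesion, 3319 for the high dose and 1961 for the low dose. These were, with run as a fixed block, 148, 2077 and 703, and 4 of 15, 1 of 18 and 4 of 17 named genes lost their call, among them Fos (adjusted p = 0.0515) and Penk (0.12) for the lesion.

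The last comparison set the levodopa effects against the lesion effects across 13271 genes, which are not independent replicates. The correlation was -0.28 for the high and -0.33 for the low dose in dSPN, and -0.31 and -0.40 in iSPN (Spearman -0.27, -0.33, -0.31 and -0.39). In the fit with run as a fixed block these were -0.17, -0.36, -0.26 and -0.05. The shared saline arrays alone gave -0.49, -0.50, -0.56 and -0.56 in simulated unchanged genes. When the shared arrays were split between both effects the correlation was -0.17, -0.20, -0.01 and -0.04. The covariance was -0.0443, -0.0411, -0.0375 and -0.0427. By the fit, which takes the spread alike in both lines, the shared arrays account for -0.0168 in dSPN and -0.0263 in iSPN. Lesioned saline arrays were less alike in iSPN (median correlations 0.9438 to 0.9624) than in dSPN (0.9736 to 0.9762). The shared part in iSPN may thus be larger in size than the fit gives. With split arrays it was -0.0315 (SD 0.00301), -0.0287 (SD 0.00278), -0.000891 (SD 0.00738) and -0.00548 (SD 0.00548). These SDs are over splits of the same arrays and give no error of the covariance. Of the genes called after the lesion, 172 were called in the opposite direction at the high dose and 163 at the low dose in dSPN (70.7 and 53 if independent). In iSPN these were 176 and 125 (40.3 and 17.1), and the overlaps too rest on shared saline arrays. Among them were Vgf, Nr4a3, Egr2, Dusp14 and Arc in dSPN, and Nr4a1, Vgf and Scg2 in iSPN.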

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

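The tests of the explanations in this part were chosen after the results were seen, except the other splits of the arrays and the test of array scaling for Penk. Each comparison was set beside 99 other splits of its arrays. For the lesion in dSPN the real count was 329 and the highest other 2, so it ranked 1 of 100, as did the high dose in dSPN (6056 against 3532), the low dose in dSPN (4531 against 866), the dose comparison in dSPN (903 against 135), the lesion in iSPN (823 against 373), the high dose in iSPN (1309 against 310) and the low dose in iSPN (555 against 208). The interactions for the lesion (645 against 96), the high dose (3319 against 53) and the low dose (1961 against 990) also ranked 1 of 100. So did the line comparison (2448 against 1). No other split drawn gave as many genes, which makes a random grouping an unlikely source of these counts. Labels were exchanged without regard to run, so a run difference is not covered. For the interactions they were exchanged within both lines at once. Those ranks speak to an effect in either line and not to a difference between lines alone. For the dose comparison in iSPN 5 of 100 splits gave 23 genes or more, up to 153, so chance cannot be excluded.

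Pattern A is that Ttc12 was far lower in dSPN than in iSPN (-7.74) and Sfxn1 higher (2.82). Sfxn1 is the first measured gene on a side of Drd1 and Ttc12 the first on a side of Drd2, so neighbours carried on the transgenes could explain both. These were 2 of 10 tested nearest neighbours that stood over 1 higher in the line of their driver, against 0 of 10 next ones, while 425 of 13271 genes in all differed by over 1. The pattern was chosen because of these genes, so this count is no independent test, and a true difference between the cell types stays untested. A faulty Sfxn1 probe set was excluded, since the lower value of its probe sets was 2.82 and the other gave 2.95, but for Ttc12 it stays open, since 1 probe set with a difference of 7.74 in size measured it.

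Pattern B is the rise of Pdyn and Tac1 in iSPN after high-dose levodopa. A constant share of dSPN RNA in the iSPN samples (11.1% from Pdyn, 95% interval 6.85% to 17.5%) stays open. Observed minus needed changes had a median of 0 over 20 genes, with 4 short by over 2 SE, such as Egr1 (-0.33 observed, 0.11 needed). Eya1 stood at 0.992% of its dSPN level. Of 3437 genes with a dSPN level above 9, it alone lay below the lower limit of the share by over 2 SE. Genes that iSPN also make can stand above that limit without carried-over RNA, so the genes above it do not favour the share. Tac1 rose by more than that share gives with all arrays (0.49, 95% interval 0.20 to 0.82) and without its outlying array (0.35, 0.14 to 0.54), but with run as a fixed block the excess was 0.23 (-0.08 to 0.54), so the share as the whole of the Tac1 rise is not excluded. A rising amount of dSPN RNA as the whole of the Pdyn rise was argued against by 7 of 11 markers. These fell short by over 2 SE, such as Drd1 (-0.33 observed, 0.39 needed). Sfxn1 of pattern A is among the 7, and its needed change rests on its level in the Drd1 line. The median over the 11 was -0.57 (SE 0.31), and a rising amount as a part of the rise is not excluded. Whether iSPN themselves make more of these peptides is untested.

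Pattern C is the rise of Penk in dSPN after the lesion. More iSPN RNA as the whole of the rise was argued against, with a median of observed minus needed changes of -0.52 (SE 0.21) over 10 markers. Of these, 7 were short by over 2 SE, such as Drd2 (-0.23 observed, 1.91 needed). More iSPN RNA as a part of the rise is not excluded. The rise was 0.58 with median centring and 0.62 with quantile normalization. The deposited values were already nearly alike in distribution, so rescaling them could hardly move it. A scaling effect built into the deposited values is therefore not excluded. A rise of Penk within dSPN is left as a hypothesis that was not tested by another method.

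The lesion response differed between the lines in 645 genes. Towards dSPN stood Sulf1 (2.79), Tnnt2 (2.69), S100a10 (2.64), Rapgef3 (2.63), Gpx6 (2.54) and Penk (0.37). Towards iSPN stood C030013G03Rik (-4.95), Vgf (-3.79), Anxa3 (-3.71), Cartpt (-3.69), Mir670hg (-3.44), Nr4a1 (-3.35), Fos (-3.05), Arc (-1.58) and Egr1 (-0.56). The high-dose response differed in 3319 genes, with Nr4a3 (5.33), Shisa2 (4.92), Tinf2 (4.68), Nr4a1 (4.59), Nptx2 (4.52), Fos (4.07), Arc (3.59), Fosb (2.59), Th (2.37), Egr1 (1.38), Junb (1.15) and Penk (0.53) towards dSPN. Towards iSPN were Rnd1 (-3.65), Rapgef3 (-3.37), Fam117a (-3.27), Notch2 (-3.18), Musk (-3.00) and Drd2 (-0.74). For Notch2 only 1 of 2 probe sets above the filter went this way. The low-dose response differed in 1961 genes, with Nr4a3 (4.94), Shisa2 (4.36), Apold1 (4.17), Tinf2 (4.10), Pcsk1 (4.09), Nr4a1 (3.92), Fos (3.27), Arc (2.94), Fosb (2.26), Egr1 (1.39), Junb (0.83) and Penk (0.30) towards dSPN. Towards iSPN were Rapgef3 (-3.28), Mcm6 (-2.64), S1pr5 (-2.57), Fam117a (-2.49) and Tmem86a (-2.48). With run as a fixed block the calls of Rapgef3 (adjusted p = 0.614), Gpx6 (0.252), Penk (0.12) and Fos (0.0515) for the lesion, of Drd2 (0.151) for the high dose and of Rapgef3 (0.509), Mcm6 (0.123), Fam117a (0.102) and Penk (0.481) for the low dose were lost.

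Single arrays stood apart from the rest of their group in 4 of 60 sets of values, where chance gives about 1 in 20, or 3. The 60 sets were 12 genes in the 5 groups of up to 10 arrays, and the 3 larger groups were not searched. These were Drd2 in replicate 5 of iSPN after low dose (11.9, nearest 12.2), Tac1 in replicate 7 of iSPN after lesion with saline (8.44, nearest 9.26), Arc in replicate 7 of dSPN after mock lesion (8.07, nearest 7.41) and Nr4a1 in replicate 2 of iSPN after mock lesion (9.25, nearest 7.91). Without its array the lesion change of Tac1 in iSPN was -0.27 (adjusted p = 0.106) and no longer called, while its rises after high dose (0.61, 2e-05) and low dose (0.45, 0.00371) were. The lesion changes of Arc in dSPN (-0.66, 0.0432) and Nr4a1 in iSPN (3.05, 6.97e-14) kept their call, and Drd2 after low dose in iSPN stayed uncalled (-0.03, 0.967).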

How the results depend on the processing

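The tests without each array (apart from those single in their group and run), without arrays of low weight and with the marker covariate were chosen after the results were seen. No paired analysis was possible because each array came from a different mouse and the labels give no pairs. Run and group overlap in part, and runs lie within a line. With run as a fixed block the counts were 88 (lesion), 1847 (low dose) and 174 (doses) in dSPN, 106 (lesion), 249 (high dose) and 0 (doses) in iSPN, and 148, 2077 and 703 for the interactions of lesion, high and low dose. That block also turned the dose shifts in iSPN of oxidative phosphorylation (adjusted p = 0.239, 3.09e-05 to 0.239 over 8 settings) and of the proteasome (0.599, from 0.011 to 0.599 over 8 settings) downward, gave covariances beyond shared arrays of -0.0175 and -0.0112 (dSPN, high and low dose) and -0.00447 and -0.00733 (iSPN, high and low dose), and kept 348 of 536 named genes. Of 99 list calls 78 held with that block, 19 were lost and 2 turned. Of 108 list calls quantile normalization lost 13, the mean of all probe sets 11 and fry 17, with 42 gained by fry. A random block gave 158 genes for the doses in iSPN and a covariance beyond shared arrays of -0.0271 (dSPN, low dose). With each line fitted on its own arrays the counts were 554 (lesion, dSPN) and 350, 577, 153 and 3 (lesion, high dose, low dose and doses, iSPN). The pooled fit takes 1 spread per gene for both lines. Arrays were less alike within groups of iSPN (lowest median correlation 0.939) than of dSPN (0.9695). Pooled counts therefore do not compare the lines, and with lines fitted apart the lesion called more genes in dSPN than in iSPN. The arrays of 1 run gave 7 (lesion, dSPN, 5 against 4), 7 (doses, dSPN, 2 against 11), 61 (high dose, iSPN, 8 against 2) and 4 (low dose, iSPN, 8 against 4). They kept 118 of 306 named genes, and 102 of these were from the high dose in dSPN, where 109 were called. Loss of calls from fewer arrays is not told apart from an effect of run. The fit within 1 run could not be done for the low dose in dSPN nor for lesion and doses in iSPN. The mean of all probe sets gave 42 genes for the doses in iSPN and 0.13 for Gphn after low dose in dSPN (adjusted p = 0.438), against -0.29 and a range of -0.31 to 0.13 over 10 settings. Array weights gave 776 (lesion) and 1375 (doses) in dSPN and 438 (lesion) in iSPN. Without the 4 arrays of weight under 0.5 the high dose in iSPN gave 855. With the oligodendrocyte marker mean as a covariate the doses in iSPN gave 15 and the lines 426. No filter gave covariances beyond shared arrays of -0.0199 and -0.0178 (dSPN, high and low dose) and the strict filter -0.0348 and -0.0299, with more and fewer genes. Without single arrays the doses in iSPN gave 12 (without high-dose replicate 2) to 53 genes (without low-dose replicate 8), among these 15 without low-dose replicate 3 and 39 without low-dose replicate 1. The cause of these differences was not tested.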

Other observations

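The genes and families in this part and their tests were chosen after the values were seen. Clock genes moved with levodopa in dSPN: of 19 measured, 5 rose and 11 fell at the high dose and 5 rose and 9 fell at the low dose, with camera adjusted p = 0.108 and 0.0955 as lists. Per1 rose by 1.66 (SE 0.14) and 1.20, Per2 by 1.76 (SE 0.16) and 1.56, Bhlhe40 by 1.40 and 1.45 and Nfil3 by 1.49 and 1.08. Nr1d1 (-1.28 and -1.30), Dbp (-1.28 and -1.21) and Arntl (-1.73 and -0.51) fell, and Arntl was 1.23 lower at the high than at the low dose. In iSPN the high dose lowered Per1 (-0.72, adjusted p = 0.00219) and raised Nfil3 (0.84), Ciart (0.70) and Tef (0.41, adjusted p = 7.68e-05), which fell in dSPN (-0.52). The response differed from that of dSPN for Per1 (2.37), Per2 (1.58), Bhlhe40 (1.86), Nr1d1 (-1.18), Dbp (-1.50), Arntl (-1.31) and Tef (-0.94). The lesion in iSPN lowered 6 of 19 clock genes, with Ciart at -0.99 and Dbp at -0.42 (camera adjusted p = 0.00294, and adjusted p = 0.0116 with an estimated correlation), and in dSPN it lowered Per2 (-1.02, SE 0.16, adjusted p = 8.94e-06). The hour at which the striatum was taken is not given in the sources used here.

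Further families were tested in every comparison. In the lesion interaction protocadherins (camera adjusted p = 0.00582, or 0.0441 with an estimated correlation) and histone lysine enzymes (0.00261, or 0.0441) stood towards dSPN, with no called member. Vacuolar proton pump subunits stood towards iSPN there, with 1 of 16 called (0.00582, or 0.0469). After the lesion protocadherins and histone enzymes had medians of -0.26 and -0.21 in iSPN (camera adjusted p = 0.00614 for both, or 0.0616 and 0.0998 with an estimated correlation). In dSPN the medians were 0.08 and 0.11, and neither family passed. In the dose comparison of iSPN kinesins shifted down with no called member (0.00237, or 0.0352). Within dSPN no list call among these families held with an estimated correlation. At the high dose 10 of 26 protocadherins fell and none rose (camera adjusted p = 0.0304, or adjusted p = 0.119 with an estimated correlation), 8 of 16 subunits of the vacuolar proton pump rose and none fell (0.0182, or adjusted p = 0.119 with an estimated correlation), and 16 of 25 histone lysine methyltransferases and demethylases fell with 3 risen (0.0182, or adjusted p = 0.119 with an estimated correlation). Of 29 kinesins 11 fell and 3 rose, which did not pass (0.108), and 45.6% of all genes were called in this comparison. At the low dose 7 protocadherins fell (0.0221, or adjusted p = 0.14 with an estimated correlation) and 14 histone enzymes fell with 3 risen (0.0254, or adjusted p = 0.146 with an estimated correlation). Pump subunits (5 risen) and kinesins (10 fallen and 1 risen) did not pass there (0.0588 for both).

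The shared saline arrays leave open how much levodopa reverses the lesion. By the fit, with the spread taken alike in both lines, the covariance beyond those arrays was -0.0276 and -0.0243 in dSPN and -0.0112 and -0.0163 in iSPN. With run as a fixed block these were -0.0175, -0.0112, -0.00447 and -0.00733. With split arrays the covariance was -0.0315 and -0.0287 in dSPN, and -0.000891 and -0.00548 in iSPN. In iSPN the split values were smaller in size than those of the fit, so a reversal there rests on the equal spread. Saline arrays from further mice, used for the levodopa side alone, would bear on this.

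The comparison of the lines rests on arrays that share no run, and lower oligodendrocyte markers in dSPN go with it. Mock-lesioned mice of both lines purified together would separate line from run.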
